A study of Homo sapiens with 12 samples.

How the data were processed

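RNA sequencing was carried out by the study on HT-29, a human colorectal cancer cell line, and on LAD2, a human mast cell line, each grown alone or in direct coculture with the other line for 12 hours. Total RNA was taken with a mini column kit from HT-29 and with a micro column kit from LAD2, per the labels. The labels give neither the medium of the coculture nor the way in which the lines were separated before extraction. Each of the 4 groups has 3 columns in the deposited table. The deposited values are raw counts per gene without normalization, and the processing notes of the authors name FastQC 0.11.9, STAR 2.7.10a, DESeq2 3.24.0 and the genome build hg38. The program that counted reads per gene and the annotation are not given in the sources used here.

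The table held 58721 genes and 12 columns. Its identifiers lacked the dot and 1 character of the version suffix, so that 12826 of them kept a stray digit. The same characters were removed from the identifiers of GENCODE release 29, and each of the 58721 identifiers of the table then equalled 1 of that release. GRCh38 (hg38) coordinates came from that release, and 58252 genes had a current symbol. The 3 columns of LAD2 coculture held the same count in every gene, while the columns of every other group differed from each other. These 3 columns were therefore counted as 1 library, which left 10 distinct libraries and a comparison of 1 LAD2 coculture library with 3 LAD2 alone libraries, instead of the 3 against 3 of the labels. In that comparison the lone library was assumed to vary like the libraries of LAD2 alone. The test of the difference used 1 estimate of the spread for all groups. HT-29, which varied less than LAD2, gave most of the replicates, so those p-values may be too small for the LAD2 side. Nothing states that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples.

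Total counts were 19.6 M, 34.1 M and 17.2 M (M, 1e6 counts) for HT-29 alone and 29.6 M, 23.5 M and 18.4 M for HT-29 coculture. They were 20.5 M, 20.8 M and 22.6 M for LAD2 alone and 25.4 M for LAD2 coculture. A count of 0 allows up to 3 counts, which is 0.088 to 0.174 counts per 1e6 counts (CPM) per library. Folds against a group with 0 counts were computed against 3 counts over the group and are lower bounds, and ratios with 1 to 3 counts have exact Poisson intervals at 95%. Intervals and floors cover counting error only. Reads shared between near-identical or overlapping genes could not be checked, which leaves TPSAB1 and TPSB2, HLA genes, ribosomal proteins, and the overlapping pairs BGN and HAUS7 and CMPK2 and RSAD2 uncertain.

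Each line was fitted alone in edgeR 4.0.16 under R 4.3.3 with TMM normalization, filterByExpr, the two-sided quasi-likelihood F test and Benjamini-Hochberg (BH) adjustment, and genes with an adjusted p under 0.05 were called. The biological coefficient of variation was 1.7% in HT-29 and 4.03% in LAD2. The difference between the responses of the lines was tested as an interaction over the 10 libraries, as the LAD2 response minus the HT-29 response. Of 40 lists fixed in advance, 38 were gene groups for testing and 2 were marker lists of the lines, and 1258 of 1260 members were matched. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, 35 lists in HT-29 and 37 in LAD2, and again with an estimated correlation. In LAD2 that correlation is estimated from the spread of the 3 alone libraries only. No LAD2 list passed in that setting, even where most members were called, so it cannot tell LAD2 lists apart. Calls in the overlap of the lines were counted with the two-sided Fisher's exact test.

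RNA of the other line was measured in each library. For genes at 50 CPM or more in the other line alone and at most 0.5 CPM in the line itself, the level above the line alone was divided by the level in the other line, and the median was taken as the share. The level that a mixture of both lines at this share gives was computed for every gene from the mean profiles of the lines alone, and a gene 10-fold or more higher in the other line alone is called an other-line gene. A planned permutation test of the shares was not used, because the choice of genes nearly absent from a line alone sets the share of its alone libraries near 0.

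Named genes were chosen by a rule. It took the 10 largest rises and 10 largest falls among called genes that are not other-line genes, with a change of at least 2-fold, a mean of 5 CPM or more in a group and groups that do not overlap. It also took the 5 largest rises among other-line genes, up to 4 members with the smallest p of each list described, fixed sets of genes for each line, and the 5 most positive and 5 most negative differences. Genes without a protein name and pseudogenes were passed over, and 2 genes that the rule took for HT-29 are not reported here. The lists, this rule, the tests and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, a minimum mean of 10 CPM, the replicate number as a block and all libraries in 1 fit. They also held leaving out each library, leaving out other-line genes, subtracting the share of the other line, and 2 other ways to measure that share. Chosen after the data were examined were an offset for the mixture of the lines, subtraction with the LAD2 coculture profile and counting the identical columns as 3 libraries. So were estimated correlations for the reduced or subtracted data, the list test of the difference, and comparisons of single LAD2 libraries.

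The pipeline was tested on simulated data. Changed genes were drawn from genes at 10 CPM or more, and every gene of a line had the same dispersion. The percentages called therefore hold only for such genes. Of 100 genes changed 2-fold, 100% were called in HT-29 and in LAD2, and of 100 genes changed 1.2-fold, 91% were called in HT-29 and 25% in LAD2, with 9 and 2 unchanged genes called. Shares of 1% and 5% put in were found as 0.996% and 4.95%. With such shares as the only change, 517 genes were called in HT-29, 351 of them at 2-fold or more, and 1473 in LAD2, 941 of them at 2-fold or more. Subtraction left 5 and 87 calls, and the offset left 0 in both lines at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.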

Results

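Gene expression was measured by RNA sequencing in HT-29 colorectal cancer cells and LAD2 mast cells, each alone or after 12 hours of direct coculture with the other line. HT-29 had 3 libraries alone and 3 in coculture, LAD2 had 3 libraries alone, and LAD2 coculture had 1 distinct library because its 3 columns were identical in every gene. Total counts ranged from 17.2 M to 34.1 M (M, 1e6 counts) per library. Values are counts per 1e6 counts (CPM) with the SD where there are replicates, and fold changes are on the log2 scale with the SE of the edgeR fit.

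The comparison of HT-29 coculture with HT-29 alone asks how contact with mast cells changes the cancer cells, in particular their epithelial and mesenchymal genes. Transcripts of mast cells appeared in the HT-29 coculture libraries, while the epithelial genes stayed near their level alone. KIT, the receptor of stem cell factor (ENSG00000157404, GRCh38 chromosome 4, 54657918 to 54740715), had 0 counts in HT-29 alone and 54.8 ± 3.79 CPM (SD, n = 3) in coculture, at least 1280-fold higher. The mast cell protease CPA3 reached 38.4 ± 1.57 CPM, the tryptases TPSB2 and TPSAB1 27.3 ± 1.62 and 25.6 ± 1.77 CPM, and HDC, which makes histamine, 24.4 ± 1.68 CPM (SD, n = 3 each). All of these had 0 counts in HT-29 alone and were at least 902-, 641-, 600- and 571-fold higher. These genes are abundant in LAD2 alone, where KIT stood at 4467 CPM and CPA3 at 3292 CPM. The coculture level was 1.23% of the LAD2 level for KIT, 1.17% for CPA3, 1.06% for TPSB2, 1.05% for TPSAB1 and 1.1% for HDC.

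Over 309 genes abundant in LAD2 and nearly absent from HT-29, the share of LAD2 RNA was 1.04%, 1.09% and 1.19% in the 3 HT-29 coculture libraries (mean 1.11% ± 0.0737, SD, n = 3). The 26 mast cell markers fixed in advance had a median of 0.00488 CPM in HT-29 alone and 8.33 CPM in HT-29 coculture, against 585 CPM in LAD2 alone. The 26 epithelial markers had medians of 182 CPM in HT-29 alone and 184 CPM in HT-29 coculture. Of 29 tested mast cell identity genes, 28 were higher (28 adjusted over the list alone; adjusted p = 5.66e-60, and adjusted p = 0.0138 with an estimated correlation). Of these, 27 were other-line genes, 10-fold or more higher in LAD2 alone. With genes at 0 set to the floor, the median change of the list was 7.51, and its other-line members stood at a median of 1.17% of their LAD2 level. KIT and Fc epsilon receptor signalling genes were higher in 20 of 28 (20 adjusted over the list alone; adjusted p = 6.17e-23, and adjusted p = 0.0138 with an estimated correlation), of which 19 were other-line genes at a median of 1.2% of their LAD2 level. The median change of this list was 0.97 with genes at 0 set to the floor. Among mast cell granule and secretion genes, 13 of 26 were higher and 1 was lower (13 and 3 adjusted over the list alone; adjusted p = 3.36e-10, and adjusted p = 0.0208 with an estimated correlation), and all 13 were other-line genes. The median of this list was 0.13 with genes at 0 set to the floor. Eicosanoid synthesis and receptor genes were higher in 5 of 15 (5 adjusted over the list alone; adjusted p = 9.6e-06, and adjusted p = 0.0411 with an estimated correlation), all 5 other-line genes, with a median of 0.09 with genes at 0 set to the floor. HPGD, an other-line gene that breaks down prostaglandins, was at 18.2 ± 0.572 CPM alone and 70.4 ± 1.17 CPM in coculture (n = 3 each). As a member of the identity list it stood at most at 1.46 times the mixture, the highest value of that list. After subtraction of the share, the granule and secretion list and the KIT and Fc epsilon receptor list did not pass (adjusted p = 0.654 and 0.943), while the identity and the eicosanoid list did (adjusted p = 8.4e-12 and 0.0188). A small remainder over a gene at or near 0 alone gives a large fold. The pass of the identity list, with 14 of 29 members at 0 alone, therefore does not count against LAD2 RNA. That reason covers the eicosanoid list only in part, since HPGD was at 18.2 CPM alone. The 2 lists stood at medians of 1.05 and 1.03 times the mixture, and the eicosanoid list did not pass without other-line genes (adjusted p = 0.371).

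**Figure D1:**
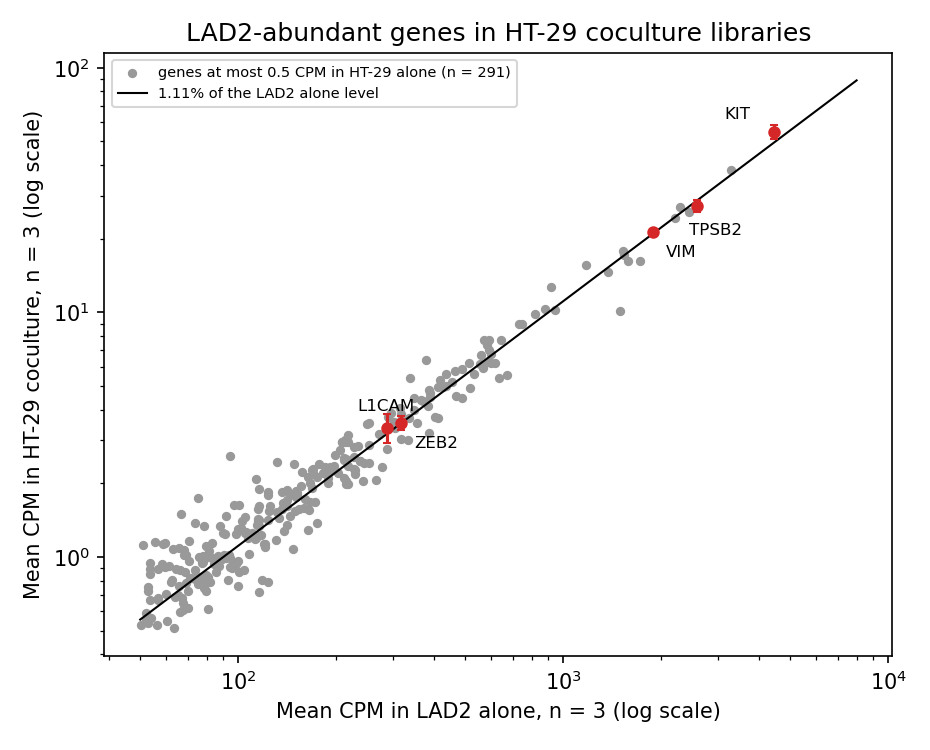
Mean CPM in HT-29 coculture (n = 3, log scale) against mean CPM in LAD2 alone (n = 3, log scale) for genes at 50 CPM or more in LAD2 alone and at most 0.5 CPM in HT-29 alone that were tested (grey points), with 5 named genes in red (bars, SD). The line marks 1.11% of the LAD2 level, and VIM and ZEB2 lie beside it with the mast cell genes KIT and TPSB2.

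Among genes used as marks of epithelial and mesenchymal state, VIM and ZEB2 were higher in HT-29 coculture, and the epithelial genes CDH1 and EPCAM changed by less than 0.1 on the log2 scale. VIM, which encodes the intermediate filament vimentin (ENSG00000026025, chromosome 10, 17228259 to 17237593), was at 0.779 ± 0.381 CPM alone and 21.2 ± 0.724 CPM in coculture (n = 3 each; log2 fold change 4.86, SE 0.132, adjusted p = 2.84e-29). ZEB2, a repressor of epithelial genes (ENSG00000169554, chromosome 2, 144364364 to 144524583), had 3 counts over the HT-29 alone libraries and 254 in coculture, a ratio of 84.1 (exact Poisson interval 28.5 to 411), and reached 3.53 ± 0.227 CPM (n = 3; adjusted p = 8.61e-18). Both genes are abundant in LAD2 alone, VIM at 1891 CPM and ZEB2 at 317.8 CPM. The rise of VIM was 1.08% of its LAD2 level and that of ZEB2 1.1%, and the observed levels were 0.978 and 0.993 times those of a mixture with 1.11% LAD2 RNA. After subtraction of that share, the log2 fold change of VIM was -0.45 (adjusted p = 0.747) and ZEB2 was too low to be tested.

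CDH1, the adhesion protein E-cadherin (ENSG00000039068, chromosome 16, 68737225 to 68835548), fell slightly from 457.8 ± 4.64 to 441.2 ± 3.49 CPM (n = 3 each; log2 fold change -0.07, SE 0.0199, adjusted p = 0.0244). This call was lost in 9 of 16 other settings, among them subtraction (log2 fold change -0.046, adjusted p = 0.248). EPCAM, an epithelial surface protein, was at 745.6 ± 6.25 and 737.3 ± 15.1 CPM (adjusted p = 0.446). SNAI1, a repressor of CDH1, was at 3.1 ± 0.329 CPM alone and 3.11 ± 0.131 CPM in coculture (adjusted p = 0.943). The adjusted p was 0.606 for the matrix protease MMP7 and 0.808 for fibronectin (FN1). CDH2, SNAI2, ZEB1, TWIST1 and MMP9 were too low to be tested. Of 44 tested epithelial junction and identity genes, 2 were higher and 6 lower (3 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.0546). ELF3, an epithelial transcription factor, rose from 51.8 ± 3.59 to 61.4 ± 0.666 CPM (n = 3 each), while the desmosomal genes PPL and DSG2 fell by 0.13 and 0.10 on the log2 scale. Mesenchymal genes were higher in 5 of 19 and lower in 1 (5 and 4 adjusted over the list alone; adjusted p = 0.958), and EMT transcription factors were higher in 1, ZEB2, and lower in 1, HMGA2, of 9 (1 and 2 adjusted over the list alone; adjusted p = 0.593; the median was 0, the mean 0.5, and the test pointed down). Among the mesenchymal genes, S100A4 stood at 1.07 times the mixture. BGN, a matrix proteoglycan whose gene overlaps HAUS7, was at 0.016 CPM in LAD2 alone and rose by 0.14 (adjusted p = 0.00231).

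**Figure D2:**
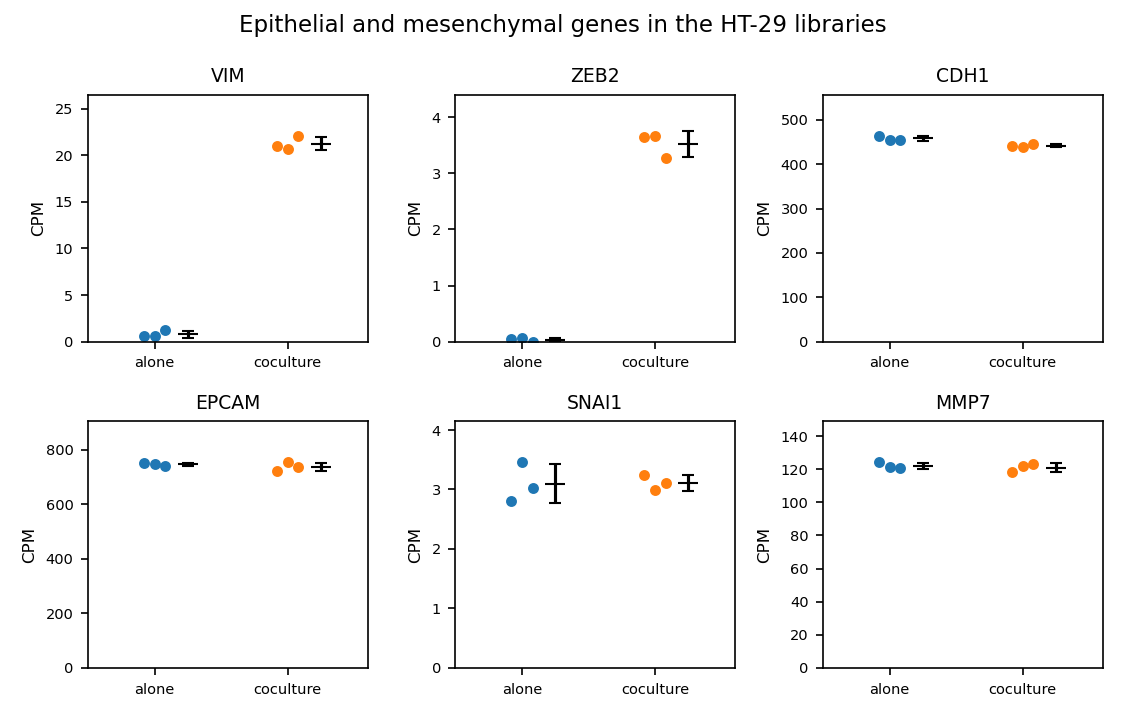
CPM of VIM, ZEB2, CDH1, EPCAM, SNAI1 and MMP7 in each HT-29 library, alone (blue) and in coculture (orange), with the mean and SD of each group in black (n = 3 each). VIM was at 0.779 CPM alone and 21.2 CPM in coculture, and CDH1 at 457.8 and 441.2 CPM.

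Partial EMT genes, which mark cells with mixed epithelial and mesenchymal features, were higher in 3 and lower in 12 of 27 (3 and 13 adjusted over the list alone; adjusted p = 0.00589, and adjusted p = 0.292 with an estimated correlation). The list had a median of -0.06 and a mean of 0.25, because the 3 higher members, L1CAM, ITGA5 and EMP3, are other-line genes, at 1.04, 0.937 and 0.88 times the mixture. Without other-line genes the median of the list was -0.09 (adjusted p = 3.86e-06, and adjusted p = 0.186 with an estimated correlation). After subtraction it was -0.11 (adjusted p = 2.49e-06). Integrins and adhesion receptors were higher in 10 and lower in 6 of 27 (10 and 8 adjusted over the list alone; adjusted p = 0.204), and matrix proteases and inhibitors were higher in 6 and lower in 6 of 26 (7 and 7 adjusted over the list alone; adjusted p = 0.288). The other-line members PLAT, TIMP3 and ADAM12 of the protease list stood at 0.852, 0.974 and 0.866 times the mixture. PVR, an adhesion receptor and ligand of lymphocyte receptors, fell by 0.20 on the log2 scale (adjusted p = 8.39e-10). ERK pathway output genes and EGFR ligands were lower in 7 and higher in 1 of 29 (11 and 1 adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.429 with an estimated correlation). Among them, ERRFI1, a feedback inhibitor of EGFR, fell from 210.8 ± 6.48 to 179.8 ± 4.87 CPM, and PHLDA1, FOSL1 and TGFA fell by 0.16, 0.18 and 0.16 on the log2 scale. KITLG, the ligand of KIT (ENSG00000049130, chromosome 12, 88492793 to 88580851), with 0 CPM in LAD2 alone, fell from 350.5 ± 5.53 to 308.6 ± 7.63 CPM (n = 3 each; adjusted p = 2.6e-09).

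Genes of sterol synthesis rose together in HT-29 coculture. Of 25 tested cholesterol synthesis and SREBP2 target genes, 20 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median of 0.18 (adjusted p = 1.52e-13, and adjusted p = 0.0399 with an estimated correlation, which was 0.0663 without other-line genes). INSIG1, which holds back sterol synthesis when sterols are plentiful (ENSG00000186480, chromosome 7, 155297776 to 155310235), rose from 118.6 ± 1.38 to 153.8 ± 4.92 CPM (n = 3 each; adjusted p = 8.34e-15). The synthesis enzymes HMGCS1, DHCR7 and IDI1 rose by 0.26, 0.21 and 0.23 on the log2 scale (adjusted p = 2.21e-13, 3.67e-10 and 1.07e-09). LAD2 alone expressed HMGCS1 at 2439 CPM, and all 25 members of the list stood at or above the mixture with 1.11% LAD2 RNA, at a median of 1.11 times it. After subtraction of that share the median was 0.15 (adjusted p = 1.58e-17).

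Interferon-stimulated genes were higher in 14 and lower in 0 of 45 in HT-29 coculture (17 and 0 adjusted over the list alone; adjusted p = 4.79e-09, and adjusted p = 0.302 with an estimated correlation). Of the 14, 13 were other-line genes, at a median of 1.34 times the mixture with the LAD2 alone profile. XAF1 and RSAD2 reached 2.45 ± 0.393 and 2.59 ± 0.181 CPM, 1.55 and 1.98 times that mixture. The list also passed without other-line genes (adjusted p = 0.000179, median 0.08, and adjusted p = 0.51 with an estimated correlation) and after subtraction (adjusted p = 1.11e-06). The 1 higher member that is not an other-line gene, IRF7, an interferon regulatory factor chosen after its values were seen, rose from 27 ± 1.78 to 32 ± 2.1 CPM (n = 3 each; adjusted p = 0.00363). Antigen presentation genes were higher in 8 of 21 (12 adjusted over the list alone; adjusted p = 4.93e-06, and adjusted p = 0.0399 with an estimated correlation), 6 of them other-line genes, with HLA-B at 1.06 times the mixture, and the list did not pass without other-line genes (adjusted p = 0.0703) or after subtraction (adjusted p = 0.282). G2 and M phase genes were lower in 4 of 42 (4 adjusted over the list alone; adjusted p = 0.00452, and adjusted p = 0.302 with an estimated correlation), among them the division genes ANLN and CDC25B, by 0.11 and 0.10 on the log2 scale. Cytosolic ribosomal proteins were lower in 2 of 57 (0 adjusted over the list alone; adjusted p = 0.00589, and adjusted p = 0.677 with an estimated correlation), and nuclear-encoded respiratory chain genes in 2 of 49 (1 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.429 with an estimated correlation). The ribosomal and the respiratory list did not pass after subtraction (adjusted p = 0.293 and 0.282). S phase genes were lower in 1 of 41 (1 adjusted over the list alone; adjusted p = 0.565). Ribosome biogenesis and MYC target genes were lower in 6 of 31 (7 adjusted over the list alone; adjusted p = 0.0544), the lowest adjusted p of the 23 lists that did not pass.

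In all, 1233 of 14070 genes were called in HT-29, 820 higher and 413 lower. With the offset for the mixture, 192 were higher and 222 lower, and without HT-29 alone replicate 2, 269 were lower. Of the 820, 522 were other-line genes. At 2-fold or more, 381 genes were higher and 2 lower, and 378 of the 381 were other-line genes. No gene outside the other-line genes met the rule for the 10 largest rises or falls. TRIM31, a ubiquitin ligase with 0.016 CPM in LAD2 alone, was chosen after its values were seen and rose from 30.6 ± 1.53 to 49.1 ± 2.06 CPM (n = 3 each; adjusted p = 9.68e-16). AMD1, an enzyme of polyamine synthesis chosen in the same way, fell from 341.1 ± 4.02 to 260.4 ± 3.99 CPM (adjusted p = 2.25e-19). Without other-line genes, 496 genes were called (243 higher and 253 lower) and 4 of them changed 2-fold or more, and after subtraction of the share 432 were called, 24 of them at 2-fold or more.

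The comparison of LAD2 coculture with LAD2 alone asks how contact with cancer cells changes the mast cells. Interferon-stimulated genes rose and genes of sterol synthesis fell in LAD2 coculture, and the main mast cell genes stayed near their level alone. MYLIP, a ubiquitin ligase that degrades the LDL receptor (ENSG00000007944, chromosome 6, 16129125 to 16148248), rose from 8.23 ± 0.767 CPM (SD, n = 3) to 38.5 CPM in the single coculture library (log2 fold change 2.21, SE 0.103, adjusted p = 2.36e-21). IFIT1, an antiviral RNA-binding protein (ENSG00000185745, chromosome 10, 89392546 to 89406486), rose from 66.5 ± 3.83 to 207.8 CPM (adjusted p = 1.31e-23). TMEM97, a sterol-regulated membrane protein (ENSG00000109084, chromosome 17, 28319095 to 28328685), fell from 209.3 ± 7.1 to 68.5 CPM (log2 fold change -1.62, SE 0.0738, adjusted p = 1.27e-21). HT-29 alone expressed IFIT1 at 5.22 CPM and TMEM97 at 143.6 CPM.

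Of 46 tested interferon-stimulated genes, 41 were higher and 0 lower in LAD2 coculture (42 and 0 adjusted over the list alone), with a median of 0.88 (adjusted p = 1.15e-17, and adjusted p = 0.267 with an estimated correlation). The 10 largest rises by the rule were MYLIP and 9 members of this list, namely IFI44L, OAS2, MX1, OASL, IFIT1, MX2, ISG15, OAS1 and CMPK2, with log2 fold changes from 1.95 for IFI44L to 1.45 for CMPK2. ISG15, a ubiquitin-like modifier, rose from 83.9 ± 4.58 to 251.4 CPM, against 37.5 CPM in HT-29 alone. LGALS3BP, the 1 other-line member of the list that was higher, stood at 1.01 times the mixture. Antigen presentation genes were higher in 7 of 22 (9 adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.472 with an estimated correlation), among them NLRC5, TAP2 and PSMB8, by 0.71, 0.50 and 0.42.

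Of 25 cholesterol synthesis and SREBP2 target genes, 23 were lower and 0 higher in LAD2 coculture (23 and 0 adjusted over the list alone), with a median of -0.95 (adjusted p = 7.35e-17, and adjusted p = 0.158 with an estimated correlation). HMGCS1, an early enzyme of the pathway (ENSG00000112972, chromosome 5, 43289395 to 43313512), fell from 2439 ± 33.1 to 1083 CPM, and LSS, which closes the sterol rings, from 809 ± 17.5 to 329.3 CPM. The log2 fold change was -1.51 for TM7SF2, -1.35 for MVD, -1.24 for ACAT2 and -1.21 for DHCR7. Outside this list, the 10 largest falls held TMEM97, IZUMO1 with -1.48, RASIP1 with -1.34 and the transcription factor POU3F2 with -1.16. IZUMO1 and RASIP1 are neighbours on chromosome 19, where RASIP1 ends at 48740721 and IZUMO1 starts at 48740852.

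**Figure D3:**
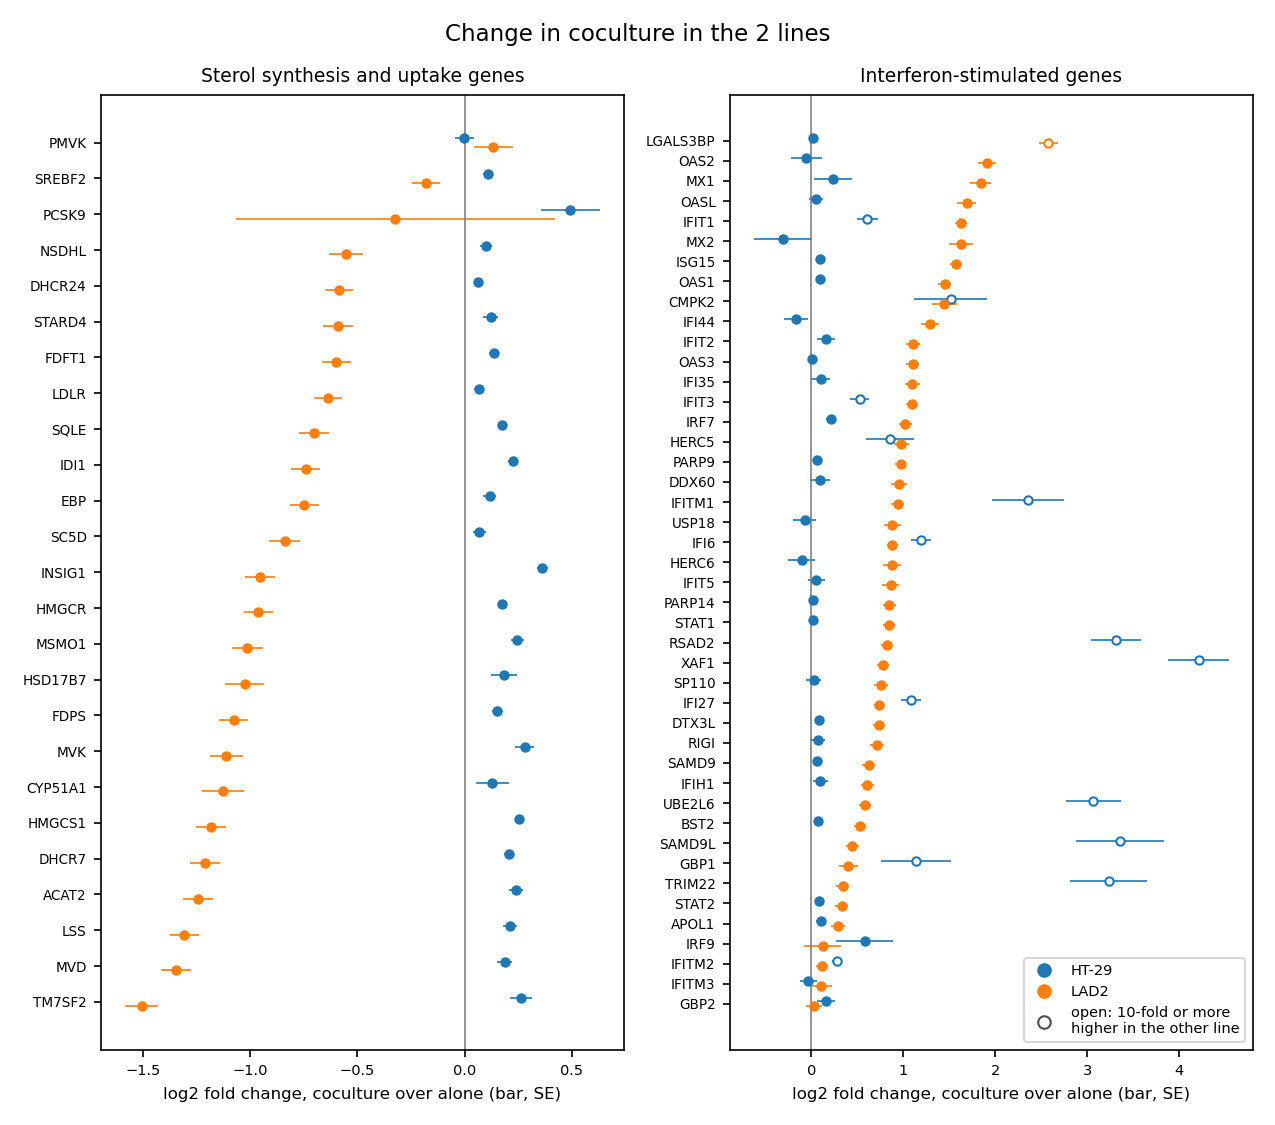
Log2 fold change of coculture over alone with its SE for the sterol synthesis list (left) and the interferon-stimulated list (right) in HT-29 (blue) and LAD2 (orange), for genes tested in both lines, with other-line genes drawn open. The LAD2 medians were -0.95 for the sterol list and 0.88 for the interferon list, and the HT-29 median of the sterol list was 0.18.

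S phase, ribosomal and early signalling genes were also higher in LAD2 coculture. The mixture accounts for part of this, as it gives the S phase list a median of 0.111 and the ribosomal protein list 0.085. After subtraction of HT-29 RNA their medians were 0.31 and 0.18. S phase genes were higher in 33 of 41 (36 adjusted over the list alone), with a median of 0.39 (adjusted p = 1.77e-10, and adjusted p = 0.141 with an estimated correlation), among them MCM4, MCM7, MCM5 and MCM3 of the replicative helicase, by 0.67, 0.48, 0.52 and 0.48. G2 and M phase genes were higher in 5 of 42 (2 adjusted over the list alone; median 0.07), and the list did not pass (adjusted p = 0.168). Cytosolic ribosomal proteins were higher in 43 of 57 (54 adjusted over the list alone; median 0.24, adjusted p = 2.01e-10, and adjusted p = 0.487 with an estimated correlation). Ribosome biogenesis and MYC target genes were higher in 21 of 31 (22 adjusted over the list alone; adjusted p = 2.96e-05, and adjusted p = 0.263 with an estimated correlation), a call that subtraction of HT-29 RNA ended (adjusted p = 0.195). Nuclear-encoded respiratory chain genes were higher in 12 of 48 (12 adjusted over the list alone; adjusted p = 0.000649, and adjusted p = 0.548 with an estimated correlation). Immediate early genes were higher in 20 and lower in 2 of 35 (22 and 3 adjusted over the list alone; adjusted p = 8.29e-07, and adjusted p = 0.141 with an estimated correlation). The transcription factor EGR1 rose from 0.939 ± 0.154 to 13.9 CPM and FOS from 0.836 ± 0.286 to 9.11 CPM. Both are other-line genes and stood at 4.09 and 4.38 times the mixture. EGR3, with 0.00976 CPM in HT-29 alone, rose from 0.127 ± 0.0594 to 3.08 CPM. ERK pathway output genes and EGFR ligands were higher in 23 of 28 (24 adjusted over the list alone; adjusted p = 2.53e-13, and adjusted p = 0.141 with an estimated correlation), 17 of them other-line genes. DUSP4, a phosphatase of this pathway, rose from 35.7 ± 0.425 to 65.4 CPM. Mitochondrially encoded genes were lower in 12 of 13 (13 adjusted over the list alone), with a median of -0.42 (adjusted p = 3.95e-06, and adjusted p = 0.472 with an estimated correlation), and their share of counts was 5.39%, 5.37% and 4.82% in LAD2 alone and 3.98% in LAD2 coculture. LAD2 alone replicate 3 differed from the other LAD2 alone libraries in the direction of the coculture by a median over 0.05 in size in 8 lists that passed. The median was -0.172 for mitochondrially encoded genes, 0.093 for ribosomal proteins, 0.088 for heat shock, 0.068 for interferon-stimulated and 0.062 for respiratory chain genes. It was 0.055 for antigen presentation and 0.051 each for unfolded protein response and partial EMT genes. Replication-dependent histone genes were lower in 3 of 13 (3 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.263 with an estimated correlation). Glycolysis, heat shock and unfolded protein response genes were higher in 10 of 20, 8 of 20 and 9 of 23, with 1 lower in each (adjusted p = 0.0349, 0.0296 and 0.0496, and adjusted p = 0.472, 0.6 and 0.472 with an estimated correlation). Adjusted over the list alone, 10, 8 and 11 were higher. After subtraction of HT-29 RNA these 3 lists and the histone genes did not pass (adjusted p = 0.247, 0.195, 0.195 and 0.0649).

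Mast cell identity genes were higher in 1 and lower in 2 of 34 in LAD2 coculture (1 and 1 adjusted over the list alone; adjusted p = 0.405; the median was 0.01, the mean -0.01, and the test pointed down). KIT was at 4467 ± 60.4 CPM alone and 4049 CPM in coculture (adjusted p = 0.104), and the adjusted p was 0.746 for TPSAB1, 0.812 for TPSB2, 0.886 for CPA3, 0.362 for MS4A2, 1 for FCER1A and 0.111 for HDC. MRGPRX2, a receptor for basic peptides on mast cells, fell from 531.1 ± 17.3 to 441.3 CPM (adjusted p = 0.000986), a call that subtraction ended (log2 fold change -0.277 before and -0.188 after, adjusted p = 0.0517). SRGN, the proteoglycan of the granules, rose from 338.2 ± 15.3 to 417.2 CPM. Mast cell granule and secretion genes were higher in 1 and lower in 4 of 30 (1 and 4 adjusted over the list alone; adjusted p = 0.281). KIT and Fc epsilon receptor signalling genes were higher in 5 and lower in 5 of 31 (5 and 5 adjusted over the list alone; adjusted p = 0.296). Mast cell activation genes were higher in 11 and lower in 2 of 22 (11 and 2 adjusted over the list alone; adjusted p = 0.00585, and adjusted p = 0.263 with an estimated correlation), 4 of the 11 other-line genes. The chemokine CCL2 rose from 5.78 ± 0.255 to 8.47 CPM (adjusted p = 0.00745) and the nuclear receptor NR4A1 from 16.9 ± 0.805 to 24.4 CPM (adjusted p = 7.45e-05). CXCL8, an other-line gene with 0 counts in LAD2 alone, was at 0.946 CPM in coculture, at least 20.2-fold higher and 1.73 times the mixture. PTGS2 did not pass (adjusted p = 0.547), and TNF and IL13 were too low to be tested.

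Transcripts of HT-29 were present in the LAD2 coculture library. Keratin 18 (KRT18, ENSG00000111057, chromosome 12, 52948871 to 52952901) had 1 count in LAD2 alone and 6777 in coculture. MET, the receptor of hepatocyte growth factor, KLK6, ST14 and MARCKSL1 had 0 counts in LAD2 alone and were at 40, 33.4, 32.2 and 31.7 CPM in coculture, at least 852-, 711-, 685- and 674-fold higher, and at 0.873, 1.29, 0.945 and 0.912 times the mixture. Over 327 genes abundant in HT-29 and nearly absent from LAD2, the share of HT-29 RNA was 5.26% in LAD2 coculture (percentiles 5 and 95 of the genes, 3.26% and 7.33%). The 26 epithelial markers had a median of 0.0162 CPM in LAD2 alone and 11.8 CPM in LAD2 coculture. Epithelial junction and identity genes were higher in 34 of 41 (35 adjusted over the list alone; adjusted p = 1.63e-22, and adjusted p = 0.141 with an estimated correlation), all 34 of them other-line genes at a median of 5.35% of their HT-29 level, and the list did not pass without other-line genes (adjusted p = 0.716). Colon differentiation genes were higher in 16 of 20, Wnt targets and intestinal stem cell genes in 14 of 17 and partial EMT genes in 18 of 26, with 16, 14 and 17 of them other-line genes, and 0, 0 and 4 were lower. Adjusted over the list alone, 18, 14 and 19 were higher (adjusted p = 2.04e-14, 1.3e-08 and 3.39e-08, and adjusted p = 0.141 for each with an estimated correlation). Matrix proteases and inhibitors were higher in 12 of 27, integrins and adhesion receptors in 14 of 30, TGF-beta response genes in 14 of 25 and NRF2 target genes in 10 of 24, with 9, 12, 9 and 7 of them other-line genes, and 2, 5, 1 and 0 were lower. Outside other-line genes, 2 integrin and adhesion genes were higher and 5 lower, and 1 partial EMT gene was higher and 4 lower. Adjusted over the list alone, 15, 15, 14 and 11 were higher (adjusted p = 0.00115, 0.0176, 2.61e-05 and 0.000838, and adjusted p = 0.244, 0.263, 0.158 and 0.355 with an estimated correlation). Without other-line genes, of these 4 lists the TGF-beta response genes passed (adjusted p = 0.0276, and adjusted p = 0.465 with an estimated correlation). After subtraction, the Wnt, partial EMT, integrin and NRF2 lists did not pass (adjusted p = 0.195, 0.137, 0.223 and 0.21). The epithelial, colon differentiation, matrix protease and TGF-beta lists still passed (adjusted p = 8.88e-05, 3.51e-11, 0.0267 and 0.00811). Remainders over genes at or near 0 give large folds. The epithelial and colon differentiation passes therefore do not count against HT-29 RNA. That reason covers the matrix protease list only in part, with 4 of 27 members at 0 alone and 3 higher members that are not other-line genes. Without other-line genes the matrix protease list did not pass (adjusted p = 0.663). That reason does not cover the TGF-beta list, where 5 higher members were not other-line genes. Its median without other-line genes was 0.15. The 4 lists stood at medians of 0.973, 1.13, 1.02 and 1.08 times the mixture.

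In all, 3298 of 15821 genes were called in LAD2, 2230 higher and 1068 lower, and 1058 of the 2230 were other-line genes. With the offset for the mixture, 469 were higher and 533 lower, and with all libraries in 1 fit, 6998 and 446. Without LAD2 alone replicate 1 or 3, 674 and 1674 were lower. At 2-fold or more, 1013 genes were higher, 968 of them other-line genes, and 70 were lower. Without other-line genes 1898 genes were called (1122 higher and 776 lower), and after subtraction of the share 1583 were called. The coculture group rests on 1 library, and with the identical columns counted as 3 libraries the number of calls was 6816.

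The comparison of the responses asks whether the lines changed differently in coculture, and its LAD2 side rests on 1 coculture library. Sterol genes rose in HT-29 and fell in LAD2, and interferon-stimulated, S phase and ribosomal protein genes were higher in the LAD2 response. Without genes 10-fold different between the lines, the median difference (LAD2 minus HT-29) was -1.15 for cholesterol synthesis and SREBP2 target genes (adjusted p = 8.4e-35, and adjusted p = 0.00616 with an estimated correlation). It was 0.82 for interferon-stimulated genes (adjusted p = 9.83e-19, and adjusted p = 0.1 with an estimated correlation), 0.39 for S phase genes (adjusted p = 4.85e-18, and adjusted p = 0.0113 with an estimated correlation) and 0.25 for cytosolic ribosomal proteins (adjusted p = 8.7e-19, and adjusted p = 0.399 with an estimated correlation). In the fit of all 17435 genes, MYLIP differed by 2.45 (SE 0.128, adjusted p = 1.41e-23). There, TM7SF2 differed by -1.60 (SE 0.0842, adjusted p = 1.81e-23) and TMEM97 by -1.50 (SE 0.0664, adjusted p = 6.49e-27). These values were not corrected for the shift of that fit, where the median of all differences was 0.17. In the fit without genes 10-fold different between the lines, 2077 of 12241 genes differed, 1236 with a higher and 841 with a lower response in LAD2. Over all 17435 genes 7117 were called, 5877 with a higher and 1240 with a lower response, but the median of all differences was then shifted to 0.17. With DESeq2 size factors, where that median was 0.03, 5106 were called, 3343 higher and 1763 lower. The larger direction turned with no filter (1744 higher and 2109 lower) and without HT-29 alone replicate 1 (2038 and 2716), HT-29 alone replicate 3 (2061 and 2741) or HT-29 coculture replicate 3 (1954 and 2962).

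Among 12880 genes tested in both lines, genes called in opposite directions were more frequent than independent lists give. RNA of each line in the other pushes genes in opposite directions, since it raises a gene in 1 line and dilutes it in the other. Dilution is small, at most -0.08 on the log2 scale for a LAD2 gene at the median share. In HT-29 the mixture gives the epithelial list a median of -0.016, while the called falls in HT-29 had a median of -0.105. These values argue against dilution as the source of HT-29 falls of that size. The genes called in opposite directions were not examined on their own. How many opposite calls RNA of the other line gives was not counted, so the number expected without a response is not known. There were 194 genes higher in HT-29 and lower in LAD2 where 56.8 were expected (Fisher's exact p = 3.43e-57) and 204 lower in HT-29 and higher in LAD2 where 69.5 were expected (Fisher's exact p = 7.4e-55). Genes higher in both numbered 122 where 138 were expected (Fisher's exact p = 0.134), and genes lower in both 7 where 28.7 were expected (Fisher's exact p = 1.01e-06). Over 10900 genes without those 10-fold different between the lines, the numbers were 64 and 81 in opposite directions, where 14.9 and 27.7 were expected, 23 higher in both and 7 lower in both. After subtraction of the shares, genes higher in both (50 where 13.9 were expected, Fisher's exact p = 6.99e-16) and lower in both (17 where 8.14 were expected, p = 0.00345) were also more frequent than independent lists give, beside 41 and 31 in opposite directions, where 9.93 and 11.4 were expected.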

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

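The tests of single explanations in this part, the list test of the difference and the comparisons of single LAD2 libraries were chosen after the results were seen. The results below were picked out because the measured responses of the lines differed in a test of the difference itself, given as LAD2 minus HT-29 on the log2 scale. The LAD2 side of every gene and list here rests on 1 coculture library, and a deviation of that library stays open for all of them.

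The 10 genes named for the difference were the immunoglobulin variable gene ENSG00000231292 (4.19), HSPB9 (4.13), CXCL10 (2.76), EFR3B (2.56) and MYLIP (2.45), with the higher response in LAD2, and DLX1 (-5.68), HAUS7 (-2.2), CYP2D6 (-1.73), TM7SF2 (-1.6) and TMEM97 (-1.5), with the lower response. In HT-29 alone and LAD2 alone, HAUS7 was at 1.24 and 0.751 CPM, CYP2D6 at 0.472 and 1.03 CPM, DLX1 at 0.494 and 0.297 CPM, and the first 4 genes named lay under 0.7 CPM. Differences of genes this low, such as -5.68 for DLX1, are fitted values near the floor and not exact. In the LAD2 coculture library 3 counts are 0.118 CPM. The 10 differences come from the fit of all 17435 genes and were not corrected for its median difference of 0.17. In the separate fit of genes less than 10-fold different between the lines, 2077 of 12241 differed.

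Of 32 lists tested for the difference, 13 passed. The median difference was -1.15 for cholesterol synthesis and SREBP2 target genes, 0.82 for interferon-stimulated genes, 0.55 for ERK pathway output genes and EGFR ligands, 0.39 for S phase genes and 0.29 for immediate early genes. It was 0.28 for ribosome biogenesis and MYC target genes, 0.25 for cytosolic ribosomal proteins, 0.13 for nuclear-encoded respiratory chain genes, 0.12 for heat shock genes, 0.11 for unfolded protein response genes, 0.08 for glycolysis genes, 0.07 for G2 and M phase genes and -0.41 for mitochondrially encoded genes. With an estimated correlation, the sterol list (adjusted p = 0.00616), S phase genes (adjusted p = 0.0113) and ERK pathway output genes (adjusted p = 0.0432) passed, and the other 10 had an adjusted p from 0.1 to 0.577. After subtraction of the shares, heat shock genes did not pass (adjusted p = 0.359).

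Sterol synthesis genes moved in opposite directions in the lines. With an estimated correlation the rise in HT-29 passed (adjusted p = 0.0399, and adjusted p = 0.0663 without other-line genes). The fall in LAD2 did not pass, and neither did any other LAD2 list in that setting. The setting therefore does not rank the rise above the fall. HT-29 RNA in the LAD2 coculture library does not account for the fall. The mixture gives the list a median of -0.052 where -0.94 was observed, and dilution gives a LAD2 gene at most -0.08 at the median share. LAD2 RNA in the HT-29 libraries does not account for the rise, since 25 of 25 members stood above the mixture. A deviation of the single LAD2 coculture library may contribute to the fall (the LAD2 alone library farthest from the others differed by a median of -0.034), and a difference of medium and a response of the cells to each other stay open and untested.

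Interferon-stimulated genes were higher in LAD2 coculture, a call that was lost with an estimated correlation, as was every other list call in LAD2. HT-29 RNA does not account for this, since the mixture gives the list a median of -0.06 where 0.89 was observed, and 38 of the 41 higher members were no more abundant in HT-29 alone or HT-29 coculture than in LAD2 alone. A deviation of the single coculture library cannot be told apart from a response to coculture, because there is 1 library. The LAD2 alone library farthest from the others differed by a median of -0.092. A response of the mast cells to the cancer cells and a difference of medium stay open and untested.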

How the results depend on the processing

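The offset for the mixture, subtraction with the LAD2 coculture profile, counting identical columns as 3 libraries and estimated correlations for reduced or subtracted data were chosen after the results were seen. In HT-29 (1233 calls), there were 733 with the DESeq2 Wald test, 646 at a mean of 10 CPM or more, 496 without other-line genes, 432 after subtraction, 424 after subtraction with the LAD2 coculture profile and 414 with the offset. At 2-fold or more (383), there were 635 with no filter, 687 with all libraries in 1 fit, 11 at 10 CPM or more, 4 without other-line genes, 24 after subtraction, 22 with the LAD2 coculture profile and 5 with the offset. In LAD2 (3298), there were 1954 with the Wald test, 1831 at 10 CPM or more, 7444 with all libraries in 1 fit, where the median change was 0.18, 1898 without other-line genes, 1583 after subtraction, 1002 with the offset and 6816 with identical columns as 3. At 2-fold or more (1083), there were 74 at 10 CPM or more, 98 without other-line genes, 366 after subtraction and 95 with the offset. For the difference (7117), there were 4248 with the Wald test, 3853 with no filter, 2077 without genes 10-fold different between the lines and 2608 after subtraction. Fewer genes were tested without other-line genes or at 10 CPM; elsewhere the cause was not tested.

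Leaving out each library gave 925 to 1270 calls in HT-29 (369 to 445 at 2-fold or more), 2499 to 4447 in LAD2 (1040 to 1096) and 4754 to 7786 for the difference. Without HT-29 alone replicate 1, HT-29 alone replicate 3 or HT-29 coculture replicate 3, the difference gave 4754, 4802 and 4916 calls, and the median of all differences turned to -0.09, -0.09 and -0.10. The fixed markers gave an HT-29 share of 6.29% in LAD2 coculture (5.26%). Leaving out LAD2 coculture was not run because it has 1 library, nor was the replicate block for LAD2.

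Against 12 lists in the main test of HT-29, the lists that passed (newly passing ones included) numbered 6 with an estimated correlation, 6 without other-line genes, 0 with both, 7 after subtraction with the LAD2 coculture profile, 2 after subtraction with an estimated correlation, and 10 to 14 leaving out each library. Against 23 in LAD2, there were 0 with an estimated correlation, with other-line genes or without them, 17 without other-line genes at the preset correlation (16 of the 23, and G2 and M phase genes), 14 after subtraction and 20 to 23 leaving out each library. The HT-29 replicate block gave 1398 genes and 12 lists. Equal replicate numbers had correlations of 0.061, 0.043 and 0.102 across 9183 genes, and unequal numbers -0.085 to 0.034. Every sample correlated best with its own number, a hint from the data and not from the design, but not every correlation was over 0.1, so the samples were taken to share only a number. Among values of named genes, 505 in HT-29 and 488 in LAD2 stayed on the same side of the threshold across other settings with no turn of a called change, 48 in HT-29 and 21 in LAD2 lost a call and 8 in LAD2 gained one. Genes higher in both lines (122) numbered 23 without genes 10-fold different and 50 after subtraction, and genes lower in both (7) numbered 17 after subtraction.

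Directions turned in HT-29 for VIM (-0.448 after subtraction), EMP3 (-0.62 after subtraction, -0.257 with the offset, -0.264 with the LAD2 coculture profile), HLA-E (-0.041, -0.042 and -0.058 in the same order), CTSD (-0.017 with the LAD2 coculture profile) and IFI6 (-0.285 with that profile), all other-line genes. None of these turned values was called (edgeR adjusted p from 0.108 to 0.811), so they are lost calls and not falls. Without other-line genes, the mast cell granule list pointed down in HT-29 (adjusted p = 0.322; adjusted p = 0.659 with an estimated correlation), as did in LAD2 the partial EMT list (adjusted p = 0.244; 0.603) and the integrin list (adjusted p = 0.367; 0.649; 0.223 after subtraction). Without HT-29 alone replicate 1, mitochondrially encoded genes passed in the HT-29 list test with the opposite sign (adjusted p = 0.00878), and the cause was not tested. Without any other library, their adjusted p was 0.204 to 0.915, with the opposite sign also without HT-29 coculture replicate 2. Depth limits genes under about 1 CPM, where 3 counts are 0.088 to 0.174 CPM.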

Other observations

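The tests of LAD2 RNA, of exchanged reads, of VIM and ZEB2 and of the LAD2 coculture profile in this part, and the splits of LAD2, were chosen after the results were seen, while the splits of HT-29 were chosen before.

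Some gene groups not described above changed little in HT-29 coculture. Hypoxia response genes were higher in 4 and lower in 3 of 26 (adjusted p = 0.629; the median was -0.01, the mean 0.2, and the test pointed down), with the glucose transporter SLC2A1 at 546.8 ± 12.8 CPM alone and 500 ± 6.41 CPM in coculture and NDRG1 at 38 ± 2.37 and 31.2 ± 0.984 CPM (SD, n = 3 each). TGF-beta response genes were higher in 4 and lower in 2 of 27 (adjusted p = 0.99), and PMEPA1 fell by 0.14 on the log2 scale. Wnt targets and intestinal stem cell genes were higher in 1 and lower in 1 of 19 (adjusted p = 0.407), but passed after subtraction of the LAD2 share (adjusted p = 0.0236, median 0.03), and the Wnt inhibitor DKK1 fell by 0.14 on the log2 scale. NF-kappaB target genes were higher in 5 of 30 (adjusted p = 0.288), among them SAT1, which degrades polyamines and rose from 33.1 ± 1.57 to 40.6 ± 1.88 CPM. Immediate early genes were higher in 2 and lower in 7 of 32 (adjusted p = 0.288; the median was -0.02, the mean 0.07, and the test pointed down), and JUN fell by 0.18 on the log2 scale. In LAD2 coculture, monocyte and macrophage markers were higher in 1 of 6 (adjusted p = 0.423) and B and T lymphocyte markers in 1 of 5 (adjusted p = 0.844).

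LAD2-abundant genes were higher in HT-29 coculture. LAD2 RNA in these libraries is a candidate source, since 97% of 134 other-line genes stood within 1.5-fold of the mixture. These genes were not used to measure the share, were taken whether called or not, and would lie outside that range if unchanged. Reads exchanged evenly among all libraries do not account for it, since the 26 fixed mast cell markers stood at a median of at most 0.00196% of their LAD2 level in an HT-29 alone library, against at least 1.13% in HT-29 coculture. An exchange that spared the HT-29 alone libraries was not tested. For VIM and ZEB2, a rise within the HT-29 cells cannot be told apart from LAD2 RNA, since 6 of 6 values lay within percentiles 5 to 95 of the LAD2-abundant genes. At percentile 5, up to 9.74 CPM of VIM and 1.62 CPM of ZEB2 would be left to HT-29, against 0.779 and 0.0366 CPM alone. These percentiles include the counting error of genes down to 50 CPM in LAD2 alone. The room they leave is therefore an upper limit and may be too wide for the more abundant VIM. VIM stood at 1.11%, 1.09% and 1.17% of its LAD2 level where the median shares were 1.04%, 1.09% and 1.19%.

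Interferon-stimulated genes of HT-29 coculture stood above the mixture, at a median of 1.34 times it over the 13 other-line members that were called higher and 1.06 times it over all 45. With the LAD2 coculture profile in place of the LAD2 alone profile, the median of the 13 was 1.05. CMPK2, at 0.686 CPM in HT-29 coculture, stayed at 1.73 times that mixture. After subtraction with that profile RSAD2 and IRF7 were still called higher, by 1.53 and 0.193 on the log2 scale. RSAD2 was at 2.59 CPM in HT-29 coculture and 1.215 times that mixture, so its 1.53 is a small remainder over a low level alone. RNA of LAD2 cells whose interferon-stimulated genes had risen may therefore account for part of the excess, a hypothesis found and tested on the same libraries. How LAD2 RNA came into the HT-29 libraries was not tested.

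The 6 HT-29 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 1233 genes, the highest other split 0, and 1 of the 10 splits called as many as the real one. Every other split mixes alone and coculture libraries, which puts the difference between them into the spread. Its 0 calls therefore do not measure chance. Of the 4 distinct LAD2 libraries, each was set against the other 3, also too few for such a share. The coculture library gave 3298 calls and the highest other choice 0, so that 1 of 4 choices called as many. In the other choices the coculture library lies among the 3, so the same limit holds for their 0 calls. With each LAD2 alone library set against the other 2, there were 2, 0 and 197 calls.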
